A study of Mus musculus with 20 samples.

How the data were processed

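RNA was measured by sequencing in 20 libraries of sorted mouse DN3 thymocytes from C57BL/6 mice, in 6 groups. Per the labels, MxCre and DeltaMxCre (3 libraries each, 1 mouse per library) came from mice that carried the interferon-inducible MxCre alone or with floxed Zmiz1, 8 weeks after 5 injections of pI-pC. IgG and AntiNRR (3 libraries each) came from mice given control antibody or an antibody against the negative regulatory region (NRR) of Notch1 for 24 h. The number of mice behind the antibody libraries is not given in the sources used here, so p-values for these groups measure spread between samples. TamCre and DeltaTamCre (4 libraries each, 1 mouse per library) came from mice that carried the tamoxifen-inducible Rosa26CreERT2 alone or with floxed Zmiz1, 43 to 44 h after tamoxifen. Per the labels' protocols, MxCre, DeltaMxCre, IgG and AntiNRR were prepared with the SMARTer Ultra low input kit from 50 ng of RNA, and TamCre and DeltaTamCre with the TruSeq mRNA v2 kit from 100 ng, so kit and model cannot be told apart. The labels' gate for these cells reads CD44-positive and CD25-negative, whereas textbook DN3 cells are the reverse. In the libraries, Il2ra, which encodes CD25, lay between 543 and 5886 CPM and Cd44 between 0.551 and 7.23 CPM.

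Per the submitters' processing notes, reads were checked with FastQC 0.10.0, aligned to mm10 with TopHat2 2.0.9 and Bowtie2 2.1.0.0, and quantified with Cufflinks and Cuffdiff 2.1.1. Annotation, strand setting and counting options are not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies such as the ribosomal protein genes with their processed pseudogenes, are therefore uncertain. The count table holds expected counts that the authors estimated with Cuffdiff, although its sheet name speaks of raw counts. Of its values, zeros included, 98.38% are whole numbers, and 98.46% of the values above 0 lie within 0.01 of one. The authors' deposited table holds group-mean FPKM, per the file headers, with no value under 1. Its fold change is a ratio of perturbed to control group, per the file headers. Its p-value and q-value columns are also from the authors, per the file headers. The count table held 23284 genes, of which 23191 had mm10 coordinates and 22 lacked an Entrez identifier. A check of all 190 pairs of libraries, within and between groups, found no duplicate. Total expected counts per library were 11695668 to 19133149 in the SMARTer libraries and 52615332 to 101425251 in the TruSeq libraries.

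Counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood F test, Benjamini-Hochberg adjustment). A gene was called at an adjusted p (FDR) under 0.05, and "rose" and "fell" are used for genes and lists that passed. The SMARTer libraries shared 1 fit of 12 libraries and the TruSeq libraries 1 fit of 8. A gene's SE therefore draws on its spread within all groups of the fit, also those outside the comparison. The difference between the DeltaMxCre and AntiNRR effects was tested in the fit of 12, and the other 2 differences in a fit of all 20. Standard errors (SE) belong to log2 fold changes, and SDs to CPM across the libraries of a group, with a prior count of 2 where CPM were put on the log scale. The median SE of a log2 fold change was 0.28 for DeltaMxCre, 0.281 for AntiNRR and 0.114 for DeltaTamCre. On counts simulated from the fitted means, dispersions and library sizes, 2-fold changes were recovered for 42%, 34% and 72% of changed genes in these comparisons, with 8.4%, 6.5% and 4.8% of calls false. The simulation drew each gene on its own, with 50 genes per fold. It holds no structure shared by samples, so these shares may not carry over to the real libraries. Overlaps of calls were tested with a 1-sided Fisher's exact test per direction, which takes genes as independent and does not measure spread between libraries.

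Groups of genes came from 27 fixed lists, of which 25 had at least 3 tested members: Notch pathway and targets, MYC targets and nucleolar genes, cytosolic ribosomal proteins, S phase, mitosis, T lineage transcription factors, pre-TCR and recombination, beta-selection, early thymic progenitor, mature alpha-beta, gamma-delta, NK and innate lymphoid, B cell, myeloid, dendritic cell, erythroid and platelet, thymic epithelial, the PIAS-like family, p53 targets, interferon-stimulated, BCL2 family, immediate-early and heat-shock, glycolysis, cholesterol synthesis, and ATF4 and amino acid genes. Of 554 list members, 533 had data, 7 of them under other symbols. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with that correlation estimated per list, and with fry. A list's adjusted p is over the lists of its comparison, and a list is said to pass or not by camera at the preset correlation unless another test is named. Counts of members "adjusted over the list alone" use the edgeR p-values of the list's members only. A value given "without" a library is from the same fit with that library left out.

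The comparisons, tests, lists and rule for naming genes were chosen before the data were examined. The rule took 10 genes named by the study's subject, up to 8 rising and 8 falling genes by size of change (mean log2 CPM of at least 3, no overlap between groups), up to 4 per list and up to 8 per direction of an overlap or difference by p. Not every gene so named is described, some results are not reported here, and H2-Q8 and Olfr1507, from families with near-identical members, were left out. Alternatives planned with these choices were RLE and upper-quartile scaling, DESeq2 1.42.0, no filter, a mean count of at least 100, other sets of libraries in the fit, replicate number as a block, each library left out in turn, a fold change tested against 1.2, and the other list tests. An FDR of 0.1, 1 surrogate variable, TamCre 1 and DeltaTamCre 2 left out together, TruSeq libraries thinned to the median depth of the SMARTer libraries, and offsets for transcript length and GC content were added after the data had been seen.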

Results

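Gene expression was measured by RNA sequencing in DN3 thymocytes, the CD4/CD8 double-negative stage at which Notch1 signalling and the pre-T cell receptor decide entry into the alpha-beta lineage. ZMIZ1 is a PIAS-like coregulator, and the series title names its interaction with Notch1. The 20 libraries formed 3 pairs of groups: DeltaMxCre (n = 3) against MxCre (n = 3), AntiNRR (n = 3) against IgG (n = 3), and DeltaTamCre (n = 4) against TamCre (n = 4). Total counts per library were 12829780 to 18348755 in DeltaMxCre, 16537447 to 19133149 in MxCre, 11695668 to 18395358 in AntiNRR and 15277568 to 18745922 in IgG. They were 52615332 to 72477238 in DeltaTamCre and 71548171 to 101425251 in TamCre. Values are mean CPM ± SD and log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p, and coordinates are mm10.

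The first comparison asked which genes differed 8 weeks after Zmiz1 deletion with MxCre. Zmiz1 itself (chromosome 14, 25457875–25666743) fell from 330.9 ± 31.2 CPM in MxCre to 123.3 ± 8.27 CPM in DeltaMxCre (log2 fold change −1.42 ± 0.11, adjusted p = 1.15e-08, n = 3 and 3). Evl, which encodes an actin regulator (chromosome 12, 108554681–108688516), rose from 11.9 ± 2.84 to 54.6 ± 7.97 CPM (2.20 ± 0.29, adjusted p = 6.31e-05). Ptk7, a Wnt coreceptor gene (chromosome 17, 46564451–46630049), fell from 36.0 ± 6.88 to 8.98 ± 0.405 CPM (−2.0 ± 0.22, adjusted p = 7.09e-06). Notch1 (chromosome 2, 26457902–26503822) was at 2955 ± 237 CPM in MxCre and 2918 ± 112 CPM in DeltaMxCre and did not pass (−0.02 ± 0.10, adjusted p = 0.962). Of 13557 genes tested, 227 rose and 172 fell, and 2239 had an unadjusted p under 0.05. Without DeltaMxCre 2 the number called was 138, and without DeltaMxCre 3 it was 173. The groups did not overlap for 2840 genes (20.95%), where chance gives 10%.

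Among the genes with the strongest rise, the glycosyltransferase gene B4galnt2 (chromosome 11, 95863559–95914960) rose by 2.21 ± 0.30 (adjusted p = 8.29e-05). Cish, a STAT5-induced inhibitor of cytokine signalling (chromosome 9, 107296659–107302784), rose by 1.85 ± 0.31 (adjusted p = 0.00108). The T cell membrane gene Ms4a4b rose by 1.80 ± 0.37 (adjusted p = 0.00658), the TGF-beta-binding gene Vasn by 1.59 ± 0.25 (adjusted p = 0.000585) and Filip1l by 1.47 ± 0.26 (adjusted p = 0.00189). Among those with the strongest fall, the homeobox gene Hoxa7 (chromosome 6, 52215623–52218573) fell by 2.81 ± 0.37 (adjusted p = 0.000124). Maged1 fell by 2.20 ± 0.30 (adjusted p = 9.67e-05), the CDC42 effector gene Cdc42ep4 by 2.15 ± 0.34 (adjusted p = 0.000585), and the Hippo pathway adaptor gene Sav1 by 2.04 ± 0.27 (adjusted p = 7.46e-05). Bcl11a, a transcription factor gene of early lymphoid progenitors (chromosome 11, 24076564–24173558), fell from 24.3 ± 7.68 to 5.96 ± 1.45 CPM (−2.03 ± 0.31, adjusted p = 0.000355). Cd44, a marker that thymocytes lose before DN3 (chromosome 2, 102811141–102901669), fell from 5.67 ± 1.75 to 0.668 ± 0.106 CPM (−3.07 ± 0.72, adjusted p = 0.0151). The Cd44 call was lost without MxCre 1 (0.0644), DeltaMxCre 2 (0.0741) or DeltaMxCre 3 (0.0887).

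Of the Notch pathway list, 1 of 14 members rose, 1 fell and 12 did not pass, and the list as a whole did not pass (median 0.06, adjusted p = 0.308). Trib2, a pseudokinase gene and Notch target, rose by 1.45 ± 0.26 (adjusted p = 0.00192). Dtx1, a Notch target that feeds back on the receptor (chromosome 5, 120680203–120711867), was at 375 ± 16.6 CPM in DeltaMxCre and 173 ± 30.2 CPM in MxCre and did not pass over all genes (1.12 ± 0.31, adjusted p = 0.1). Every DeltaMxCre library (356 to 386.3 CPM) lay above every MxCre library (138.2 to 192.5 CPM) for Dtx1. The SE of Dtx1 rests on its spread in all SMARTer groups, AntiNRR (4.95 to 15.8 CPM) included. Across the alternative settings the adjusted p of Dtx1 ran from 1.16e-05 to 0.265, with a call in 6 of 23. Adjusted over the list alone, Dtx1 (adjusted p = 0.0250) and Trib2 rose and 3 members fell, among them Notch3 (chromosome 17, 32120820–32166896; −0.36 ± 0.13, adjusted p = 0.0329). Myc (chromosome 15, 61985341–61990361) was at 87.9 ± 17.3 CPM in DeltaMxCre and 159 ± 68.8 CPM in MxCre (−0.86 ± 0.28, adjusted p = 0.151 over all genes). The direct Notch targets Hes1 (0.18 ± 0.19, adjusted p = 0.732) and Ptcra (0.15 ± 0.15, adjusted p = 0.7) did not pass. Il2ra was at 5080 ± 738 CPM in DeltaMxCre and 3415 ± 1006 CPM in MxCre (0.57 ± 0.22, adjusted p = 0.229).

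Growth-related lists fell in DeltaMxCre. Of 60 MYC target and nucleolar genes, 7 fell, 0 rose and 53 did not pass, and adjusted over the list alone 21 fell (median −0.31, adjusted p = 2.88e-11; adjusted p = 0.305 with an estimated correlation). Nop56, which encodes a core protein of the particles that modify ribosomal RNA, fell by 0.62 ± 0.11 (adjusted p = 0.00288). Of 75 cytosolic ribosomal protein genes, 15 fell, 0 rose and 60 did not pass, and adjusted over the list alone 34 fell (median −0.33, adjusted p = 3.19e-17; adjusted p = 0.305 with an estimated correlation). Rpsa fell by 0.71 ± 0.12 (adjusted p = 0.00168) and Rpl13a by 0.53 ± 0.10 (adjusted p = 0.00445). Cholesterol synthesis genes fell as a list, with 3 of 18 called (median −0.50, and −0.14 without MxCre 3, adjusted p = 2.55e-06; adjusted p = 0.305 with an estimated correlation). The sterol sensing gene Insig1 fell by 1.06 ± 0.23 (adjusted p = 0.0152; 0.0683 without DeltaMxCre 1 and 0.111 without DeltaMxCre 2). ATF4 and amino acid genes fell as a list with 1 of 15 called (median −0.45, and −0.27 without MxCre 3, adjusted p = 0.00102; adjusted p = 0.305 with an estimated correlation). Glycolysis genes fell with 3 of 18 called (median −0.28, adjusted p = 0.000891; 0.101 without MxCre 3, where the median was −0.16; adjusted p = 0.310 with an estimated correlation). S phase genes passed as a list with 0 of 30 called by edgeR at FDR 0.05 (median −0.28, adjusted p = 0.00607; adjusted p = 0.690 with an estimated correlation). This rested on MxCre 3, without which the S phase median was 0.04 and the adjusted p 0.974 (0.0561 without DeltaMxCre 3). The mitosis list did not pass (median −0.10, adjusted p = 0.816, the test pointing up).

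In the lists on T cell development, single members were called in both directions. Lef1, a TCF family transcription factor gene (chromosome 3, 131110297–131224357), fell from 312 ± 33.9 to 171 ± 13.7 CPM (−0.87 ± 0.12, adjusted p = 0.000157). The recombinase gene Rag1 (chromosome 2, 101638252–101649532) fell from 3513 ± 461 to 2041 ± 197 CPM (−0.78 ± 0.11, adjusted p = 0.000193). Tcf7, which encodes TCF1 (chromosome 11, 52246527–52283383), fell by 0.50 ± 0.11 (adjusted p = 0.00842), a call lost without DeltaMxCre 2 (0.0574) or DeltaMxCre 3 (0.0529). The CD3 chain gene Cd3d fell by 0.50 ± 0.11 (adjusted p = 0.00889; 0.0585 without DeltaMxCre 2). The T lineage transcription factor list (median 0.00, adjusted p = 0.816, 2 of 20 fell) and the pre-TCR and recombination list (median −0.08, adjusted p = 0.572, 1 of 14 rose and 2 fell) did not pass, nor did the beta-selection list (median 0.08, adjusted p = 0.308, 1 of 20 rose). Early thymic progenitor genes fell as a list with 2 of 11 called (median −1.26, also with the member at 0 in DeltaMxCre set to a floor of 3 counts over the group, adjusted p = 0.0166; adjusted p = 0.305 with an estimated correlation). The early progenitor median was −0.54 without MxCre 1 (adjusted p = 0.106), −0.62 without DeltaMxCre 1 (0.179) and −0.82 without IgG 2, IgG 3, AntiNRR 2 or AntiNRR 3. Mature alpha-beta genes rose as a list with 1 of 9 called (median 0.45, adjusted p = 0.0314; 0.188 without MxCre 1, 0.0540 without MxCre 2 and 0.0513 without DeltaMxCre 3; adjusted p = 0.305 with an estimated correlation). The mature alpha-beta median was 0.29 without MxCre 2, 0.88 without MxCre 3, 0.20 without DeltaMxCre 1 and 0.21 without DeltaMxCre 2.

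Interferon-stimulated genes rose as a list in DeltaMxCre, with 2 of 25 called and 5 adjusted over the list alone (median 0.76, adjusted p = 1.76e-07; adjusted p = 0.305 with an estimated correlation). Trim30a, an inflammasome and antiviral regulator gene, rose by 0.79 ± 0.16 (adjusted p = 0.00637). BCL2 family genes rose as a list with 2 of 13 called (median 0.27, and 0.11 without MxCre 2, adjusted p = 0.0244; 0.101 without MxCre 3 and 0.163, with a median of 0.17, without DeltaMxCre 1; adjusted p = 0.305 with an estimated correlation). The proapoptotic BH3-only gene Bmf (chromosome 2, 118528757–118549686) rose by 0.87 ± 0.14 (adjusted p = 0.000537). The survival gene Bcl2 rose by 0.58 ± 0.14 (adjusted p = 0.0187), a call lost without MxCre 2 (0.102), DeltaMxCre 2 (0.0843) or DeltaMxCre 3 (0.0701). Immediate-early and heat-shock genes fell as a list with 0 of 17 called by edgeR at FDR 0.05 (median −0.37, adjusted p = 0.0132; 0.0554 without MxCre 1, 0.112 without MxCre 3 and 0.0588 without DeltaMxCre 1; adjusted p = 0.425 with an estimated correlation). The p53 target list did not pass (median 0.09, adjusted p = 0.572, 1 of 18 rose).

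In the authors' deposited table, fold changes were 0.363 for Zmiz1 (q = 0.00251), 0.566 for Myc (q = 0.00251), 2.02 for Dtx1 (q = 0.00251) and 0.549 for Lef1 in DeltaMxCre. Of the genes called here, 398 were listed in the authors' deposited table, 398 with the direction found here and 364 of them with q under 0.1.

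The second comparison asked which genes depended on Notch1 signalling over 24 h of antibody blockade of the receptor's negative regulatory region. Dtx1 fell from 172 ± 16.5 CPM in IgG to 11.4 ± 5.70 CPM in AntiNRR (−3.94 ± 0.36, adjusted p = 0.000311, n = 3 and 3). Il2ra (chromosome 2, 11642792–11693194), the IL-2 receptor alpha chain gene and a Notch target at this stage, fell from 3544 ± 304 to 656 ± 167 CPM (−2.43 ± 0.24, adjusted p = 0.000211). Ptcra, which encodes the pre-TCR alpha chain (chromosome 17, 46755663–46763712), fell from 214 ± 12.5 to 71.2 ± 13.2 CPM (−1.59 ± 0.15, adjusted p = 5.32e-07). Zmiz1 was at 320 ± 7.54 CPM in AntiNRR and 285 ± 24.9 CPM in IgG and did not pass (0.16 ± 0.11, adjusted p = 0.515). Of 13557 genes, 225 rose and 326 fell, and 2215 had an unadjusted p under 0.05. The number called was 361 without IgG 1, 257 without IgG 2, 295 without IgG 3, 342 without AntiNRR 1 and 359 without AntiNRR 2. The groups did not overlap for 548 of the 551 called genes and for 21.73% of all genes tested, where chance gives 10%.

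**Figure D1:**
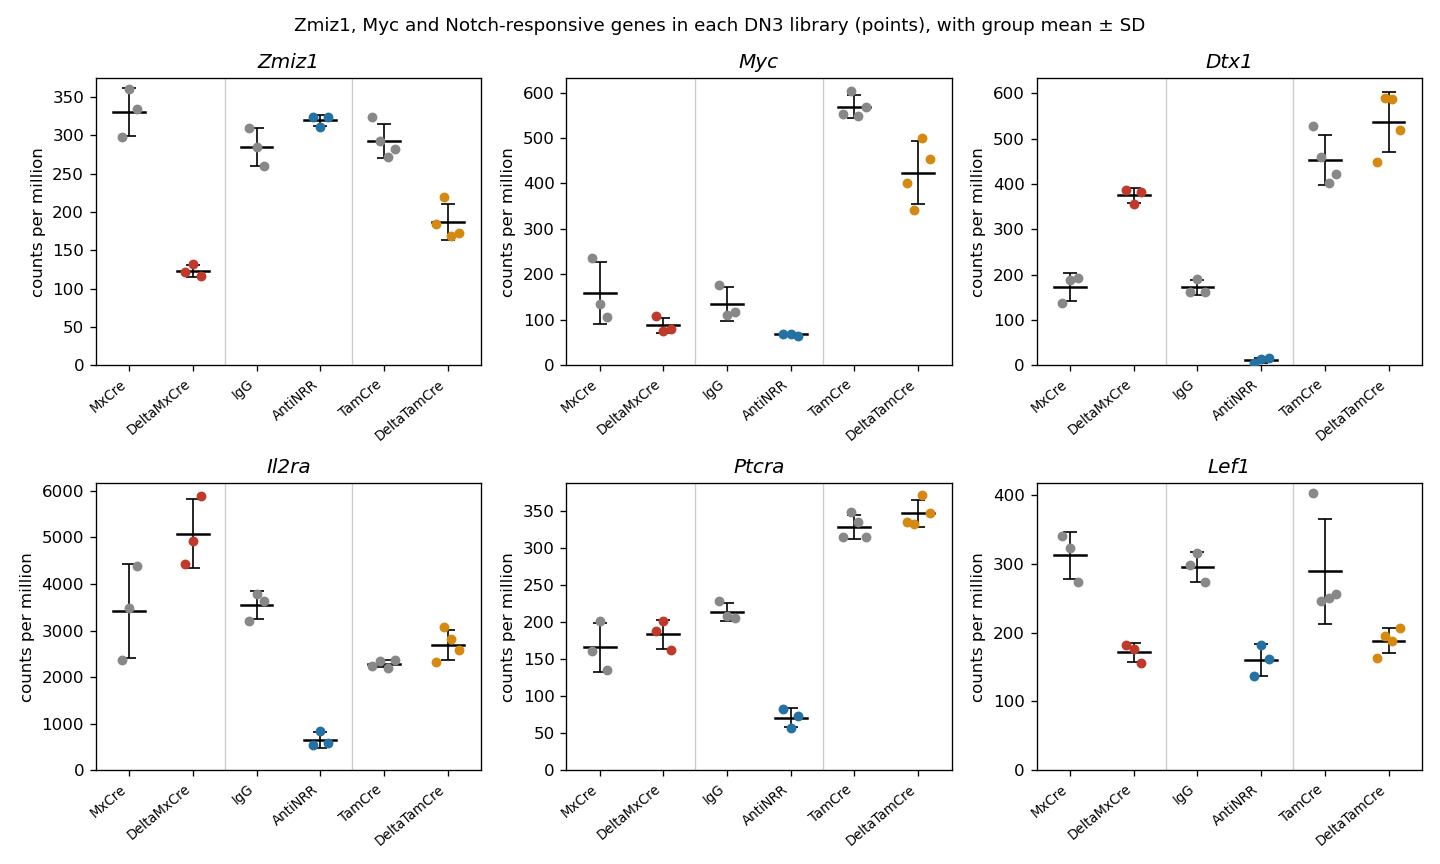
CPM in each library (points) with group mean ± SD (bars) for Zmiz1, Myc, Dtx1, Il2ra, Ptcra and Lef1 in the 6 groups. Zmiz1 was lower in every DeltaMxCre and DeltaTamCre library than in its controls, and Dtx1, Il2ra and Ptcra fell in AntiNRR.

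Of the 14 tested Notch pathway members, 7 fell, 0 rose and 7 did not pass after the antibody, and adjusted over the list alone 8 fell (median −0.75, adjusted p = 8.26e-17, and 0.00199 with an estimated correlation). Notch3 fell from 1025 to 598 CPM (−0.78 ± 0.13, adjusted p = 0.000592) and Notch1 from 3017 ± 119 to 2075 ± 190 CPM (−0.54 ± 0.10, adjusted p = 0.00187). Hes1, a repressor gene and direct Notch target (chromosome 16, 30065357–30067796), fell from 75.1 to 45.2 CPM (−0.73 ± 0.20, adjusted p = 0.0291). The Hes1 call was lost without IgG 1 (0.189), IgG 3 (0.131), AntiNRR 2 (0.0907) or AntiNRR 3 (0.144). Nrarp, a feedback inhibitor gene (chromosome 2, 25180758–25183339), did not pass (−0.45 ± 0.53, adjusted p = 0.767), and neither did Cd44 (0.19 ± 0.65, adjusted p = 0.934).

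Among the strongest falls, Mllt4, which encodes the junction protein afadin (chromosome 17, 13760391–13905798), fell from 77.9 to 5.64 CPM (−3.82 ± 0.50, adjusted p = 0.00330). The exchange factor gene Arhgef10l (chromosome 4, 140514485–140666007) fell from 172 to 14.7 CPM (−3.56 ± 0.25, adjusted p = 5.33e-06). Rasal1, a Ras GTPase-activating protein gene that ends directly before Dtx1 (chromosome 5, 120648040–120679597), fell by 2.57 ± 0.52 (adjusted p = 0.0120), a call lost without IgG 2 (0.0572) or AntiNRR 1 (0.0595). The cadherin gene Cdh23 fell by 2.32 ± 0.26 (adjusted p = 0.000131), the sodium channel subunit gene Scn2b by 1.97 ± 0.32 (adjusted p = 0.000311) and the carbonic anhydrase gene Car12 by 1.82 ± 0.35 (adjusted p = 0.00233). Il7r, a survival cytokine receptor gene (chromosome 15, 9506159–9529941), fell from 165 to 83.2 CPM (−0.99 ± 0.15, adjusted p = 0.000179). Among the strongest rises, the mast cell protease gene Cpa3 (chromosome 3, 20215616–20242209) rose from 21.6 to 125 CPM (2.54 ± 0.38, adjusted p = 0.00337). The transporter gene Slc37a3 rose by 1.76 ± 0.28 (adjusted p = 0.000281), the transcriptional coactivator gene Eya2 by 1.56 ± 0.27 (adjusted p = 0.000714) and the focal adhesion gene Tes by 1.53 ± 0.27 (adjusted p = 0.000669).

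Of 60 MYC target and nucleolar genes, 28 fell, 0 rose and 32 did not pass in AntiNRR, and adjusted over the list alone 37 fell (median −0.53, adjusted p = 9.81e-25; adjusted p = 0.0584 with an estimated correlation). The nucleolin gene Ncl fell from 1245 to 748 CPM (−0.73 ± 0.11, adjusted p = 0.000131), Nop58 by 0.80 ± 0.12 (adjusted p = 0.000146) and the nucleostemin gene Gnl3 by 0.96 ± 0.15 (adjusted p = 0.000292). Myc was at 68.2 ± 2.92 CPM in AntiNRR and 135 ± 36.8 CPM in IgG and did not pass over all genes (−0.99 ± 0.28, adjusted p = 0.0927). Ribosomal protein genes fell as a list with 3 of 75 called (median −0.25, and −0.14 without IgG 1, adjusted p = 3.80e-08; adjusted p = 0.530 with an estimated correlation). S phase genes fell as a list with 1 of 30 called (median −0.34, −0.21 without AntiNRR 1 and −0.53 without AntiNRR 3, adjusted p = 1.67e-05; adjusted p = 0.530 with an estimated correlation), and the mitosis list did not pass (median 0.06, adjusted p = 1.0). ATF4 and amino acid genes fell with 3 of 15 called and 9 adjusted over the list alone (adjusted p = 0.000108; adjusted p = 0.259 with an estimated correlation). The glutamine transporter gene Slc1a5 fell by 0.90 ± 0.18 (adjusted p = 0.00354). Glycolysis genes fell with 1 of 18 called (median −0.25, adjusted p = 0.0157; 0.0664 without IgG 1 and 0.104 without AntiNRR 2; adjusted p = 0.530 with an estimated correlation), the called member being the hexokinase gene Hk2 (−1.55 ± 0.23, adjusted p = 0.000149). The cholesterol synthesis list did not pass (median −0.02, adjusted p = 1.0).

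T lineage transcription factor genes split in AntiNRR, with 3 of 20 rising and 4 falling and no shift of the list (median 0.19, adjusted p = 0.148). Lef1 fell from 295 to 160 CPM (−0.88 ± 0.12, adjusted p = 0.000116) and Erg, an ETS factor gene of the progenitor stages, fell by 1.09 ± 0.23 (adjusted p = 0.00458). Gata3, needed for T lineage commitment, rose by 0.79 ± 0.13 (adjusted p = 0.000410), and the chromatin organiser gene Satb1 rose by 0.55 ± 0.10 (adjusted p = 0.00180). Of 14 pre-TCR and recombination genes, 3 rose and 3 fell, without a shift of the list (median −0.16, adjusted p = 0.122). Cd3d fell by 0.71 ± 0.11 (adjusted p = 0.000159) and Cd3g by 0.75 ± 0.13 (adjusted p = 0.000410). The stem cell factor receptor gene Kit rose from 103 to 184 CPM (0.84 ± 0.14, adjusted p = 0.000529). The early progenitor list (median −0.04, or 0 with a member at 0 in 1 group set to that floor, adjusted p = 0.285, the test pointing up), the mature alpha-beta list (median −0.12, adjusted p = 0.750) and the beta-selection list (median −0.02, adjusted p = 0.914) did not pass.

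p53 target genes rose as a list in AntiNRR, with 3 of 18 called (median 0.33, adjusted p = 0.0166; adjusted p = 0.266 with an estimated correlation). Trp53inp1, a stress-induced autophagy and death gene, rose by 0.63 ± 0.12 (adjusted p = 0.00146). Bmf rose by 0.83 ± 0.14 (adjusted p = 0.000332), while the BCL2 family list did not pass by camera (median 0.24, adjusted p = 0.0620) and passed by fry (adjusted p = 0.0393). The interferon list (median 0.20, adjusted p = 0.272) and the immediate-early and heat-shock list (median 0.25, adjusted p = 0.287) did not pass. In the authors' deposited table, fold changes in AntiNRR were 0.0772 for Dtx1 (q = 0.00143), 0.195 for Il2ra, 0.344 for Ptcra, 0.582 for Myc (q = 0.00143) and 1.21 for Zmiz1 (q = 0.184). Of the 551 genes called here, 549 had the direction found here in the authors' deposited table and 524 of them q under 0.1.

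The third comparison asked which genes differed 43 to 44 h after tamoxifen-induced Zmiz1 deletion. Zmiz1 fell from 293 ± 22.4 CPM in TamCre to 186.5 ± 23.4 CPM in DeltaTamCre (−0.65 ± 0.10, adjusted p = 0.0405, n = 4 and 4), and every DeltaTamCre library (169 to 220 CPM) lay below every TamCre library (272 to 324 CPM). Evl rose from 11.95 to 24.4 ± 3.08 CPM (1.03 ± 0.11, adjusted p = 0.00872). Gzma, which encodes the cytotoxic protease granzyme A (chromosome 13, 113093824–113100981), fell from 208 ± 10.6 to 129 ± 21.5 CPM (−0.69 ± 0.11, adjusted p = 0.0405). Of 13460 genes, 8 rose and 4 fell by edgeR, while 2153 had an unadjusted p under 0.05 and DESeq2 called 488. Calls numbered 2 without TamCre 1, 5 without TamCre 2, 0 without TamCre 3 (1710 at unadjusted p under 0.05), 0 without TamCre 4 (1604), 8 without DeltaTamCre 1, 5 without DeltaTamCre 2, 4 without DeltaTamCre 3 and 1 without DeltaTamCre 4.

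The other genes that rose in DeltaTamCre were the cytokine receptor gene Il31ra (1.00 ± 0.11, adjusted p = 0.00872), the microtubule-binding gene Jakmip1 (0.77 ± 0.09, adjusted p = 0.0123), the glutathione-cleaving enzyme gene Ggt5 (1.11 ± 0.16, adjusted p = 0.0405) and the myosin light chain gene Myl4 (0.70 ± 0.10, adjusted p = 0.0405). The integrin gene Itgb3 (0.68 ± 0.10, adjusted p = 0.0405), the tetraspanin gene Cd53 (0.65 ± 0.10, adjusted p = 0.0405) and the acyl-CoA synthetase gene Acsf2 (0.55 ± 0.08, adjusted p = 0.0437) also rose. The phosphoglycerate mutase gene Pgam2 fell by 0.87 ± 0.13 and the sulfhydryl oxidase gene Qsox2 by 0.51 ± 0.07 (adjusted p = 0.0405 each). Leaving out TamCre 3 raised the adjusted p to 0.0750 for Evl, Il31ra and Jakmip1, and leaving out TamCre 4 raised it to 0.0907 for Evl and Il31ra and 0.122 for Jakmip1. Leaving out DeltaTamCre 4 raised it to 0.0562 for Il31ra and 0.0690 for Jakmip1, which stood at 0.0565 without TamCre 1. Ggt5, Myl4, Itgb3, Cd53, Acsf2, Pgam2, Gzma and Qsox2 all lost their calls without TamCre 1 (adjusted p 0.105 to 0.113), TamCre 2 (0.0510 to 0.0916), TamCre 3 (0.170 to 0.213), TamCre 4 (0.135 to 0.221) or DeltaTamCre 4 (0.0740 to 0.148). All of these but Ggt5 lost them without DeltaTamCre 2 (0.0616 to 0.0662), and all but Pgam2 without DeltaTamCre 3 (0.163 to 0.197). Ggt5, Myl4, Acsf2 and Qsox2 lost them without DeltaTamCre 1 (0.0630 to 0.0926). Zmiz1 stood at 0.105 without TamCre 1, 0.0690 without TamCre 2, 0.167 without TamCre 3, 0.167 without TamCre 4, 0.0844 without DeltaTamCre 1, 0.163 without DeltaTamCre 3 and 0.137 without DeltaTamCre 4.

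Notch pathway genes did not pass as a list after tamoxifen (15 members, median −0.04, adjusted p = 0.465, the test pointing up). Dtx1 was at 536 CPM in DeltaTamCre and 453 CPM in TamCre (0.24 ± 0.11, adjusted p = 0.303), and Il2ra at 2692 ± 321 and 2290 ± 82.6 CPM (0.23 ± 0.09, adjusted p = 0.229). Hes1 (−0.08 ± 0.11, adjusted p = 0.760), Notch1 (−0.04 ± 0.11, adjusted p = 0.889) and Ptcra (0.08 ± 0.07, adjusted p = 0.617) did not pass. Heyl, a HES-related repressor gene, was 0.86 higher (adjusted p = 0.0990 over all genes) and rose when adjusted over the list alone (0.00364). Myc was at 424 ± 68.6 CPM in DeltaTamCre and 569 ± 25.0 CPM in TamCre (−0.42 ± 0.11, adjusted p = 0.133 over all genes), and fell when adjusted over the list alone (0.0157).

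MYC target and nucleolar genes fell as a list in DeltaTamCre (median −0.24, adjusted p = 7.79e-21; adjusted p = 0.383 with an estimated correlation), with 0 of 60 called over all genes by edgeR and 29 falling adjusted over the list alone. The ribosome assembly gene Nop16 (−0.35, adjusted p = 0.0224 over the list alone) and the polyamine synthesis gene Odc1 (−0.47, adjusted p = 0.0263 over the list alone) were among them. Ribosomal protein genes fell as a list (median −0.21, adjusted p = 6.89e-30; adjusted p = 0.383 with an estimated correlation), and all 74 had a negative log2 fold change. Over all genes edgeR called 0 of the 74, with Rps16 and Rpl13 at an adjusted p of 0.121 each. Adjusted over the list alone 65 fell, among them Rps16 (−0.28, adjusted p = 0.0185) and Rpl13 (−0.32). Glycolysis genes fell as a list (median −0.24, adjusted p = 9.12e-07; adjusted p = 0.613 with an estimated correlation), with 4 of 18 falling adjusted over the list alone, among them Ldha and Tpi1 (adjusted p = 0.0288 over the list alone). ATF4 and amino acid genes fell as a list (median −0.14, −0.22 without TamCre 4 and −0.23 without DeltaTamCre 3, adjusted p = 0.00501; adjusted p = 0.383 with an estimated correlation). S phase genes fell as a list (median −0.10, adjusted p = 0.00563; 0.136 without DeltaTamCre 3 and 0.222 without DeltaTamCre 4; adjusted p = 0.773 with an estimated correlation), and the median was −0.16 without TamCre 2, −0.19 without DeltaTamCre 2 and −0.05 without DeltaTamCre 4. Cholesterol synthesis genes fell as a list (median −0.10, adjusted p = 0.0255; 0.0905 without TamCre 4, 0.385 without DeltaTamCre 3 and 0.136 without DeltaTamCre 4; adjusted p = 0.740 with an estimated correlation). The cholesterol median was −0.06, −0.04 and −0.06 without these 3 libraries and −0.17 without DeltaTamCre 2. Over all genes edgeR called 0 members of the glycolysis, ATF4 and amino acid, S phase and cholesterol lists. The mitosis list did not pass (median −0.04, adjusted p = 0.238).

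Early thymic progenitor genes rose as a list in DeltaTamCre with 0 of 13 called by edgeR, over all genes or over the list alone (median 0.38, adjusted p = 0.00267; adjusted p = 0.383 with an estimated correlation), whereas they fell in DeltaMxCre (median difference 0.76, adjusted p = 0.000160; adjusted p = 0.108 with an estimated correlation). Kit was 0.34 higher (adjusted p = 0.153 over all genes). B cell genes, with all 8 members positive, did not pass by camera (median 0.42, adjusted p = 0.0795) and passed by fry (adjusted p = 0.0322). Beta-selection genes rose as a list (median 0.18, adjusted p = 0.0447; 0.0589 without TamCre 2, 0.282 without TamCre 3, 0.136 without TamCre 4, 0.0681, with a median of 0.11, without DeltaTamCre 1 and 0.129 without DeltaTamCre 4; adjusted p = 0.740 with an estimated correlation). Over all genes edgeR called 0 of the 20 beta-selection members. The TCR signalling regulator genes Cd5 (0.60, adjusted p = 0.00424) and Cd6 (0.37, adjusted p = 0.00189) rose when adjusted over the list alone. The list also holds Cd4, at 17.5 ± 11.6 CPM in DeltaTamCre and 7.55 ± 5.30 CPM in TamCre (adjusted p = 0.394), and Cd8a, at 22.02 ± 14.3 and 11.4 ± 8.55 CPM (adjusted p = 0.5), which were high in DeltaTamCre 1, 3 and 4 and in TamCre 2. Lef1 was at 188 ± 18.2 CPM in DeltaTamCre and 289 ± 76.4 CPM in TamCre (−0.62 ± 0.16, adjusted p = 0.142 over all genes) and fell when adjusted over the list alone (0.0174), as did Tcf7 (−0.32, adjusted p = 0.0174) and Cd3d (−0.49, adjusted p = 0.0113). TamCre 1 stood at 403 CPM of Lef1 and the other TamCre libraries at 246 to 256 CPM, all above DeltaTamCre (163.6 to 206.9 CPM). Across the alternative settings the Lef1 fold change ran from −0.69 to −0.42. The T lineage transcription factor list (median −0.03, adjusted p = 0.899), the pre-TCR list (median 0.08, adjusted p = 0.481) and the mature alpha-beta list (median 0.00, adjusted p = 0.779) did not pass. The p53 list did not pass (median 0.09, adjusted p = 0.465), with Trp53inp1 rising adjusted over the list alone (0.53, adjusted p = 0.00334). The interferon list (median 0.09, adjusted p = 0.140), the BCL2 family list (median 0.05, adjusted p = 0.899, the test pointing down) and the immediate-early and heat-shock list (median −0.46, adjusted p = 0.108) did not pass. The last of these rested on TamCre 1, which lay 2.04 above its group mean for that list, and without TamCre 1 the list passed pointing up (median 0.36, adjusted p = 9.25e-05). In the authors' deposited table, DeltaTamCre fold changes were 0.607 for Zmiz1 (q = 0.00246), 0.715 for Myc (q = 0.00246) and 0.643 for Lef1, and all 12 genes called here had the same direction and q under 0.1 there.

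**Figure D2:**
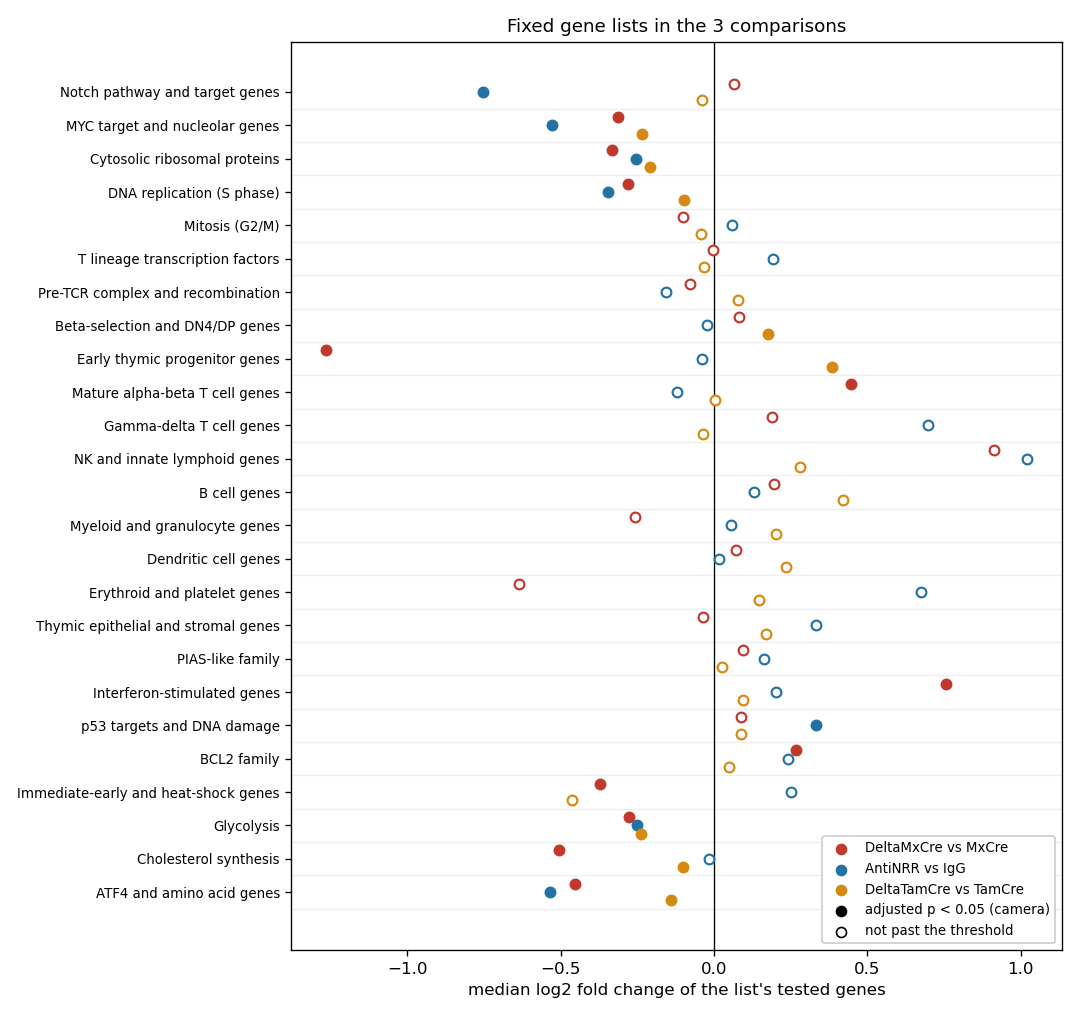
Median log2 fold change of the members of 25 gene lists in the 3 comparisons. Filled points had a camera adjusted p under 0.05, and the MYC target and ribosomal protein lists lay below 0 in all 3.

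The effects of Zmiz1 deletion and Notch1 blockade were then compared directly. Genes called in both DeltaMxCre and AntiNRR with the same direction numbered 66, of which 43 rose (3.77 by chance, 1-sided Fisher's exact p = 1.74e-33) and 23 fell (4.14 by chance, p = 2.27e-11), and 13 were called in opposite directions. Fisher's test takes genes as independent. Both comparisons also used the same estimate of spread per gene, so a gene with a low estimate is more readily called in both. The chance values do not allow for this. With only the groups compared in each fit, the shared count was 27. The opposite calls were not set against chance. By assignment of libraries to groups, shared direction gave an exact 1-sided permutation p of 0.3 for DeltaMxCre calls in AntiNRR. It was 0.1 for AntiNRR calls in DeltaMxCre. The shared count was 22 without DeltaMxCre 2, 27 without DeltaMxCre 3, 39 without IgG 2 and 41 without IgG 3. The ganglioside synthase gene St8sia1 rose by 0.96 ± 0.12 and 0.83 in DeltaMxCre and AntiNRR, the inhibitory receptor gene Clec12a by 1.08 ± 0.17 and 1.10 ± 0.17, and Cd53 by 1.26 ± 0.21 and 1.08 ± 0.21. Lef1, Nop56 and Bmf also passed in both with the same sign.

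The difference between the DeltaMxCre and AntiNRR effects passed for 167 of 13557 genes, 103 of them higher and 64 lower in DeltaMxCre. This number was 290 without MxCre 3, 99 without IgG 2 and 101 without IgG 3. Dtx1 (difference 5.06, adjusted p = 0.000890), Il2ra (3.01, adjusted p = 0.000961), Ptcra (1.73 ± 0.21, adjusted p = 1.30e-05) and Arhgef10l (3.93 ± 0.33, adjusted p = 1.33e-05) were higher in DeltaMxCre relative to control than in AntiNRR. The stromal ADP-ribosyl cyclase gene Bst1 (2.02 ± 0.19, adjusted p = 5.50e-07) and the tetraspanin gene Cd82 (1.46, adjusted p = 1.33e-05) differed in the same direction. Zmiz1 (−1.59 ± 0.16, adjusted p = 8.40e-07), the protocadherin gene Fat4 (−4.69 ± 0.51, adjusted p = 1.30e-05) and Ptk7 (−2.17 ± 0.31, adjusted p = 9.30e-05) were lower. The Notch pathway list differed (median difference 0.79, adjusted p = 5.82e-14, and 0.00325 with an estimated correlation). Of the other lists, MYC targets (0.16, adjusted p = 0.0107; adjusted p = 0.762 with an estimated correlation) and interferon genes (0.56, adjusted p = 0.00779; adjusted p = 0.762 with an estimated correlation) were higher. Early progenitor genes (−1.22, adjusted p = 0.00779; adjusted p = 0.353 with an estimated correlation) and cholesterol synthesis genes (−0.43, adjusted p = 0.00139; adjusted p = 0.762 with an estimated correlation) were lower. So were immediate-early and heat-shock genes (−0.70, adjusted p = 0.00779; adjusted p = 0.762 with an estimated correlation) and PIAS-like genes (−0.14, adjusted p = 0.0107; adjusted p = 0.584 with an estimated correlation), a list of 6 that holds the deleted Zmiz1, so that its shift was set in part by the deletion itself.

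The difference between the DeltaTamCre and AntiNRR effects passed for 97 of 13895 genes, 61 higher and 36 lower, in a fit that spans both kits. This number was 159 without MxCre 3, 47 without IgG 3 and 62 without TamCre 4. Arhgef10l (3.54 ± 0.27, adjusted p = 7.70e-08), Il2ra (2.63 ± 0.24, adjusted p = 5.81e-07), Dtx1 (4.15 ± 0.34, adjusted p = 2.36e-06) and Ptcra (1.63 ± 0.17, adjusted p = 3.39e-06) were higher in DeltaTamCre relative to control. Zmiz1 (−0.85 ± 0.15, adjusted p = 0.00282), Gata3 (−0.90 ± 0.15, adjusted p = 0.00242), Gzma (−1.59 ± 0.26, adjusted p = 0.00220) and the annexin gene Anxa2 (−0.96 ± 0.14, adjusted p = 0.000428) were lower. The Notch pathway list differed (0.64, adjusted p = 4.04e-18, and 4.56e-05 with an estimated correlation). MYC targets (0.25, adjusted p = 5.93e-06; adjusted p = 0.5 with an estimated correlation) and S phase genes (0.24, adjusted p = 0.0154; adjusted p = 0.672 with an estimated correlation) were higher. T lineage transcription factors (−0.21, adjusted p = 0.0279; adjusted p = 0.5 with an estimated correlation), NK genes (−0.94, adjusted p = 0.0475; adjusted p = 0.348 with an estimated correlation) and PIAS-like genes, Zmiz1 among them (−0.31, adjusted p = 0.00605; adjusted p = 0.312 with an estimated correlation), were lower. Cd53 and Jakmip1 (in AntiNRR 0.0603 without IgG 2) were called in both with the same sign (0.14 by chance, 1-sided Fisher's exact p = 0.00801), and this count was 1 without IgG 2, TamCre 2, DeltaTamCre 2 or DeltaTamCre 3 and 0 without TamCre 1, TamCre 3, TamCre 4 or DeltaTamCre 4.

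The 2 Zmiz1 deletions shared 7 called genes with the same direction. Evl, Cd53, Acsf2, Jakmip1 and Ggt5 rose in both (1-sided Fisher's exact p = 8.55e-08), and Qsox2 fell in both besides Zmiz1, the gene deleted in both. In DeltaMxCre the Jakmip1 call was lost without MxCre 2 (adjusted p = 0.0766), MxCre 3 (0.0827), DeltaMxCre 1 (0.0556), DeltaMxCre 2 (0.0814) or DeltaMxCre 3 (0.0954), and the Ggt5 call without any 1 of the 6 libraries (0.0501 to 0.133, the highest without DeltaMxCre 3). The shared count was 1 without TamCre 1, 3 without TamCre 2, 0 without TamCre 3, 0 without TamCre 4, 3 without DeltaTamCre 1, 4 without DeltaTamCre 2, 2 without DeltaTamCre 3 and 1 without DeltaTamCre 4. Of genes called in DeltaMxCre and tested in DeltaTamCre, 97.8% of the 225 that rose had a positive log2 fold change there, against 53.8% of all genes, and 84.3% of the 172 that fell had a negative one, against 46.2%. By group means of log2 CPM, 92.7% of all these genes kept their direction. Other assignments of the TruSeq libraries to groups reached up to 88.7%, so the share over all genes is not the value to expect by chance. The difference between the 2 effects passed for 23 genes, 19 higher and 4 lower in DeltaTamCre relative to its control. This number was 12 without MxCre 2, 52 without MxCre 3, 13 without DeltaMxCre 2, 15 without TamCre 1, 12 without TamCre 2, 13 without TamCre 3, 11 without TamCre 4 and 13 without DeltaTamCre 2. Ptk7 (1.99, adjusted p = 8.89e-05), Hoxa7 (2.76, adjusted p = 0.00156) and Sav1 (1.89, adjusted p = 0.00124) were among those that fell after MxCre deletion and differed from tamoxifen deletion.

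**Figure D3:**
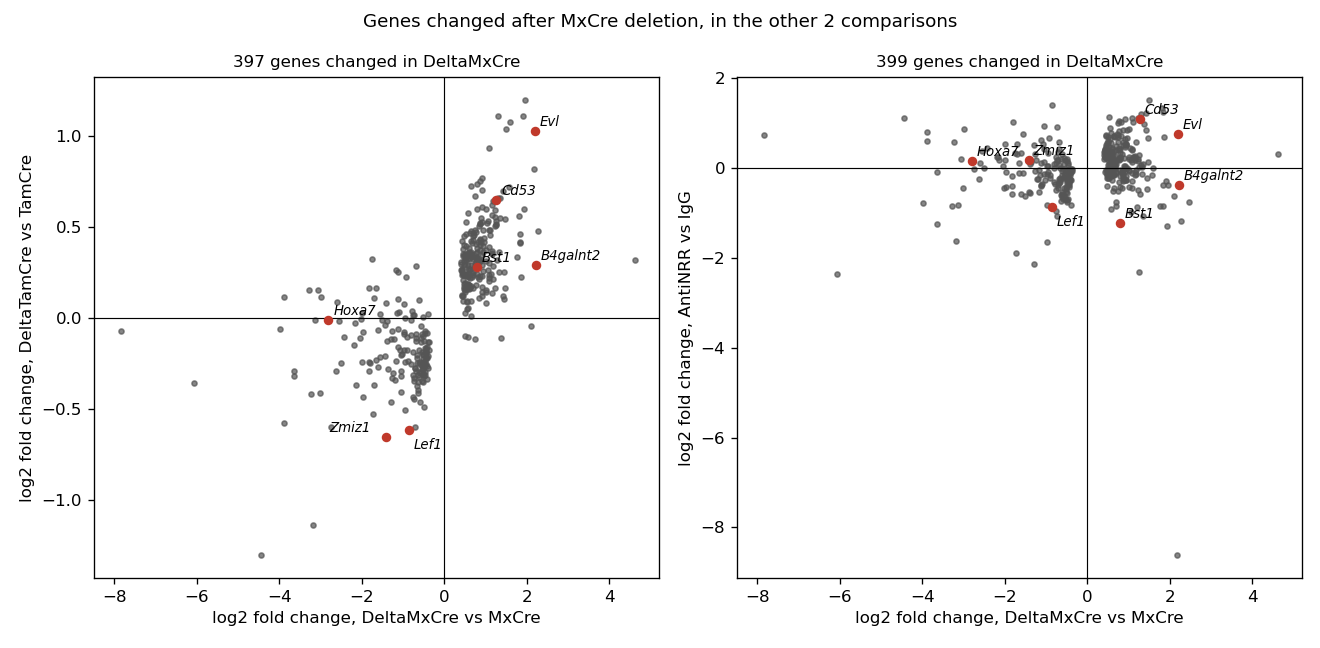
Log2 fold change in DeltaMxCre (x axis) of the genes called there against their log2 fold change in DeltaTamCre (left, 397 genes) and AntiNRR (right, 399 genes). On the left, 220 of the 225 genes that rose and 145 of the 172 that fell lay in quadrants of equal sign.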

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

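The explanations weighed here, their tests and the other splits of the samples were chosen only after the results were seen, whereas the tests of differences between comparisons were planned.

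Lower MYC target and ribosomal protein genes appeared in all 3 comparisons by camera at the preset correlation. With an estimated correlation none of the 6 list results passed (adjusted p 0.0584 for MYC targets in AntiNRR and 0.305 to 0.530 for the others). Fry passed MYC targets in DeltaMxCre (adjusted p = 0.0371) and AntiNRR (0.00202) and ribosomal proteins in DeltaTamCre (0.0112). By fry the other list results did not pass (0.0825 to 0.1745). A trend of counts with transcript length or GC content is argued against as the whole cause, since with offsets for both the medians of the 2 lists ran from −0.51 to −0.17 and stayed below 0 in all 6 cases. A larger share of ribosomal RNA precursor among the counts is argued against in DeltaMxCre, where the precursor gene Rn45s fell by 0.74 ± 0.13 (adjusted p = 0.00216, edgeR) while both lists fell. In AntiNRR, Rn45s rose by 0.90 ± 0.13 (adjusted p = 0.000149, edgeR). Before TMM scaling, which takes out a shift shared by all genes, its share of counts could lower all other genes by at most 0.06 (log2). That fall is smaller than both medians with all libraries and without each of the 12 (−0.60 to −0.14). This argues against a larger precursor share there too. Fewer dividing cells may lower growth genes, but the mitosis list had a median of −0.1 in DeltaMxCre, with a difference of library means of 0.08 ± 0.50 (SE) and a median of 0.54 without MxCre 3, and these values leave the explanation open. A lower Notch1 and ZMIZ1 input to Myc remains open as an untested biological explanation, with Myc at −0.86 ± 0.28, −0.99 ± 0.28 and −0.42 ± 0.11 in the 3 comparisons and none called over all genes by edgeR. Across the alternative settings the adjusted p of Myc ran from 0.00659 to 0.455, 0.000253 to 0.218 and 0.00985 to 1.0, with a call in 4 of 23, 6 of 23 and 2 of 20, among them DESeq2 in each comparison.

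Lower Bcl11a and Cd44 in DeltaMxCre was the second pattern. B or dendritic cells in the MxCre libraries could carry Bcl11a, but their abundant gene Cd74 reached at most 0.624 CPM there, against a loss of 18.3 CPM of Bcl11a, which argues against them for Bcl11a. Earlier Kit-high thymocytes in MxCre could carry both genes, and would make Kit lower in DeltaMxCre. Kit was instead 0.26 ± 0.14 higher there (adjusted p = 0.391 by edgeR), and 0.14 to 0.34 higher across the alternative settings. It did not pass, so such cells cannot be told apart from an effect of the deletion. The difference from the DeltaTamCre effect passed for Bcl11a (1.98, adjusted p = 0.0136; 0.0568 without MxCre 2 and 0.0639 without DeltaMxCre 2) and for Cd44 (3.19, adjusted p = 0.0136).

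The third pattern concerns the TruSeq libraries. Of the 35 splits of the 8 libraries, 2 gave at least the real count of 12 called genes, so chance is not excluded for that count, and the highest other split called 861. Such a count points to a structure of the samples: that split set DeltaTamCre 1, 3 and 4 with TamCre 2 against the others. The first principal component of deviations from group means held 50.3% of their variance. On it TamCre 1 (−18.7) and DeltaTamCre 2 (−17.9), the pair left out together, lay opposite TamCre 2 (15.7) and DeltaTamCre 1 (10.6). The remaining libraries lay between (1.1 to 4.7). Swapped labels are argued against, since TamCre 2 had 293.1 CPM of Zmiz1, above the DeltaTamCre range of 169 to 220 CPM. Carried-over CD4/CD8-positive thymocytes are a candidate explanation, since Cd4 reached 33.11 CPM in DeltaTamCre 1, 14.3 in DeltaTamCre 3, 17.4 in DeltaTamCre 4 and 15.4 in TamCre 2, against 4.42 to 5.82 CPM in the other 4 libraries. The highest SMARTer library had 15.3 CPM, above DeltaTamCre 3 and hardly below TamCre 2, so the support is weak for these 2 libraries, and the labels' gate was lineage-negative. Cd4 was also alike in TamCre 1 and TamCre 3 (5.82 and 4.42 CPM), which lay at −18.7 and 2 on the component. Against their group means, immediate-early and heat-shock genes lay at 2.04 in TamCre 1 and 0.55 in DeltaTamCre 2. The other TruSeq libraries lay at −0.84 to 0.15. Xist also separated the split, at 1588 to 2392 CPM against 657.8 to 1473 CPM. Neither was tested as an explanation.

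For the other counts, DeltaMxCre called 399 genes against at most 1 in the other 9 splits, and AntiNRR called 551 against at most 1, with 10 splits each, too few for a share under 0.05 (1 split as large in each). The difference of DeltaMxCre and AntiNRR (167 genes) exceeded the highest other of 100 splits (74), 1 split being as large. The other splits mix groups that differ, which adds to their spread and lowers their counts, so this share does not exclude chance. For the differences of DeltaTamCre from AntiNRR (97 genes, highest other 612) and from DeltaMxCre (23 genes, highest other 483), 9 of 100 splits were as large in each, and chance is not excluded. The high counts point to the structure of the TruSeq samples. The splits do not test the overlaps, since no other split of a SMARTer comparison called over 1 gene. The overlap of DeltaMxCre and AntiNRR (66 genes) had a highest other of 0, with 1 of 100 splits as large. Those of DeltaTamCre with AntiNRR (2 genes, highest other 67) and with DeltaMxCre (7 genes, highest other 44) had 2 of 100 splits as large. Keeping the SMARTer groups as they are, 3 and 2 of the 70 assignments of the TruSeq libraries shared as many, and the high counts again point to the structure of those samples. For lists, DeltaMxCre gave 11 (highest other 8, 1 of 10 splits as large) and AntiNRR 7 (highest other 7, 2 of 10), with too few splits for a share under 0.05, and DeltaTamCre gave 8 (highest other 10, 15 of 35 splits as large), so chance is not excluded there.

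Single libraries stood apart from the other 3 of their group by Dixon's ratio in 6 of 82 gene and group sets tested. Cd4, Cd8a, Jun and Hspa1a were added by hand to the genes tested and are among those that stood apart. The count can therefore not be set against chance. In TamCre 2, Cd4 was at 15.4 CPM (others 4.42 to 5.82) and Cd8a at 24.2 (6.47 to 7.64). In TamCre 1, Hspa1a was at 143 CPM (0.992 to 7.28), Jun at 382 (25.2 to 34.4), Lef1 at 403 (246 to 256) and Rpl13 at 1540 (1290 to 1320).

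The direct test of the DeltaTamCre against the DeltaMxCre effect also passed for Ptk7 (1.99, adjusted p = 8.89e-05), Sav1 (1.89, adjusted p = 0.00124), Fat4 (3.29, adjusted p = 0.00124), Hoxa7 (2.76, adjusted p = 0.00156) and Maged1 (2.01, adjusted p = 0.00644), by edgeR across kits. It passed for B4galnt2 (−1.96, adjusted p = 0.0265), Zmiz1 (0.73, adjusted p = 0.0315), Cish (−1.66, adjusted p = 0.0497) and Rag1 (0.78, adjusted p = 0.0497). The B4galnt2 call was lost without MxCre 1 (0.0855), DeltaMxCre 2 (0.0639), DeltaMxCre 3 (0.116), TamCre 2 (0.0637), TamCre 3 (0.0505), TamCre 4 (0.0586), DeltaTamCre 2 (0.0708) or DeltaTamCre 3 (0.0673). The Zmiz1 call was lost without MxCre 2 (0.0818), DeltaMxCre 3 (0.0744), TamCre 2 (0.0637), TamCre 3 (0.0899), TamCre 4 (0.0904), DeltaTamCre 1 (0.0575) or DeltaTamCre 2 (0.0708). The Cish call was lost without any 1 of 15 libraries (0.0639 to 0.187, the highest without DeltaMxCre 1), and so was the Rag1 call (0.0519 to 0.130, the highest without MxCre 2). Among lists, early progenitor genes differed by a median of 0.76 (adjusted p = 0.000160; adjusted p = 0.108 with an estimated correlation), NK genes by −1.02 (0.00262; 0.108), interferon genes by −0.67 (8.63e-09; 0.284) and cholesterol genes by 0.31 (0.00262; 0.717). Time after deletion, inducing drug and kit differ together between these models, as does the fall of Zmiz1 RNA, and these cannot be told apart.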

How the results depend on the processing

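Alternatives other than FDR 0.1, 1 surrogate variable, the pair left out, thinning and the length and GC offsets were planned, and those 5 were chosen after the results were seen. Genes called are given for DeltaMxCre, AntiNRR and DeltaTamCre (399, 551 and 12), differences for DeltaMxCre less AntiNRR, DeltaTamCre less AntiNRR and DeltaTamCre less DeltaMxCre (167, 97 and 23), and same-direction overlaps for DeltaMxCre with AntiNRR, DeltaTamCre with AntiNRR and DeltaTamCre with DeltaMxCre (66, 2 and 7).

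DESeq2 called 675 genes in DeltaMxCre and 488 in DeltaTamCre, differences 340, 312 and 88, and overlaps 110, 98 and 123, and its calls included all 399, 551 and 12 edgeR calls. With only the groups compared in the fit, DeltaMxCre gave 183, the difference of DeltaTamCre and AntiNRR 195 and the first overlap 27. With all 20 libraries in 1 fit, the comparisons gave 853, 1080 and 2, the first difference 444 and the overlaps 140, 0 and 1. Against a fold of 1.2, counts were 128, 205 and 2, differences 102, 43 and 13, and overlaps 9, 0 and 1. At FDR 0.1, counts were 718, 856 and 63, differences 303, 176 and 37, and overlaps 123, 17 and 29. With 1 surrogate variable, DeltaTamCre gave 480, the first difference 257 and the DeltaTamCre overlaps 113 and 105. Leaving out TamCre 1 and DeltaTamCre 2 together gave 30 in DeltaTamCre and 8 shared with AntiNRR, and thinning gave 4, with overlaps of 1 and 3. With an estimated correlation 0, 1 and 0 lists passed where 11, 7 and 8 had, and fry passed 3 in DeltaMxCre and 2 in DeltaTamCre. The cause was not tested for any of these.

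With the replicate number as a replicate block, edgeR called 0 genes in DeltaTamCre (1162 at unadjusted p under 0.05; DESeq2 without a block called 488), the differences from AntiNRR and DeltaMxCre gave 35 and 9 and the 2 DeltaTamCre overlaps 0 and 0. Same-numbered libraries correlated at −0.038 to −0.003 in the MxCre pair, −0.029 to 0.024 in the antibody pair and −0.357 to −0.014 in the tamoxifen pair, so the numbers were not taken to pair the samples, although ribosomal protein genes were high in replicate 1 of each SMARTer group, and the blocked fit changed no other count by over 1.5 times.

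Leaving out 1 library at a time gave 138 to 434, 257 to 817 and 0 to 8 genes, differences of 99 to 290, 47 to 159 and 11 to 52, overlaps of 22 to 76, 0 to 3 and 0 to 7, and 8 to 12, 6 to 10 and 6 to 11 lists. Lists that had not passed did so in 26 of 520 fits without 1 library, among them mitosis genes in DeltaMxCre (median 0.54 without MxCre 3) and AntiNRR (−0.65 without AntiNRR 3) and interferon genes in AntiNRR and DeltaTamCre. Signs changed for genes that passed under neither setting. Notch1 in DeltaMxCre went from −0.02 to 0 with upper-quartile scaling and 0.1 with offsets, and ran from −0.06 (without MxCre 3) to 0.05 (without MxCre 2), with 0 without DeltaMxCre 1. In DeltaTamCre, Notch1 went from −0.04 to 0.04 with a surrogate variable, 0.01 with the pair left out, 0.06 with offsets and 0.03 without DeltaTamCre 1, and ran from −0.1 (without DeltaTamCre 2) to 0.06 (without TamCre 1). Hes1 there went from −0.08 to 0.03 with the pair left out and 0 with offsets, and ran from −0.17 (without DeltaTamCre 3) to 0.01 (without TamCre 1). In AntiNRR, Nrarp ran from −1.07 (without AntiNRR 3) to 0 (without AntiNRR 1) and Cd44 from −0.05 (without AntiNRR 3) to 0.37 (without AntiNRR 1). Of the other gene values, 1651 kept direction and call, 116 lost and 59 gained a call, and with 1 library left out 1792 kept, 207 lost and 10 gained one.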

Other observations

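The tests of shared direction, of genes near Zmiz1, of replicate 1 and of Rn45s were chosen only after the results were seen, whereas the list tests were planned.

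The direction of called genes was compared across models by group means of log2 CPM with a pseudocount of 0.1, for which some shares differ from those by edgeR fold changes. Of 397 genes called in DeltaMxCre, 92.7% had the same direction in DeltaTamCre, against at most 88.7% in the other 69 assignments of the TruSeq libraries to groups (exact 1-sided permutation p = 0.0143, the smallest the design can give). Of 549 genes called in AntiNRR, 81.4% had the same direction in DeltaTamCre, against at most 81.1% (exact 1-sided p = 0.0143, the smallest the design can give). In DeltaMxCre the AntiNRR calls had the same direction for 74.8%, against at most 80.6% (exact 1-sided p = 0.1), and the DeltaMxCre calls had it in AntiNRR for 61.2%, against at most 73.2% (exact 1-sided p = 0.3). The 12 DeltaTamCre calls had the same direction for 91.7% in DeltaMxCre, against at most 91.7% (exact 1-sided p = 0.4; by edgeR fold changes 8 of 8 rising and 4 of 4 falling genes), and for 58.3% in AntiNRR, against at most 66.7% (exact 1-sided p = 0.35). Across all genes, fold changes correlated at Pearson 0.293 and Spearman 0.44 for DeltaTamCre and DeltaMxCre, 0.108 and 0.202 for DeltaTamCre and AntiNRR, and 0.01 and 0.093 for DeltaMxCre and AntiNRR.

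Marker lists of other cells did not pass by camera in the 3 comparisons, whose adjusted p are given here. Fry passed gamma-delta genes in DeltaMxCre (adjusted p = 0.0489) and AntiNRR (0.0393), NK and innate lymphoid genes in AntiNRR (0.0479) and B cell genes in DeltaTamCre (0.0322), each pointing up. NK and innate lymphoid genes had medians of 0.91 in DeltaMxCre (adjusted p = 0.252), 1.02 in AntiNRR (0.0620) and 0.28 in DeltaTamCre (0.465), although Gzma fell in DeltaTamCre, with Gzma at −0.77 ± 0.23 in DeltaMxCre (adjusted p = 0.1) and 0.86 ± 0.23 in AntiNRR (adjusted p = 0.0543). Gamma-delta genes had medians of 0.19 (0.177), 0.70 (0.223) and −0.03 (0.950), B cell genes 0.20 (0.566), 0.13 (1.0) and 0.42 (0.0795), and myeloid genes −0.26 (0.816), 0.06 (0.752) and 0.20 (0.394). Dendritic cell genes had 0.07 (0.816), 0.02 (1.0) and 0.23 (0.331), erythroid and platelet genes −0.63 (0.816), 0.67 (0.712) and 0.15 (0.883), and thymic epithelial genes −0.03 (0.612, the test pointing up), 0.33 (0.712) and 0.17 (0.883). The PIAS-like family, which holds Zmiz1, had 0.09 (0.122, the test pointing down), 0.16 (0.122) and 0.03 (0.282, the test pointing down). In DeltaTamCre Itgam of the myeloid list (1.34, adjusted p = 0.119) and Tyrobp of the NK list (1.65, adjusted p = 0.121) did not pass over all genes. Adjusted over the list alone, 1 of 10 myeloid genes rose there, and of 11 NK genes 2 rose and 1 fell.

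Genes near Zmiz1 on chromosome 14 were compared with genes elsewhere. Within 10 Mb, 5 of 105 genes (4.76%) had p under 0.01 and the same sign in both, against 1.62% elsewhere (odds ratio 3.04, 95% interval 0.954 to 7.44, 1-sided Fisher's exact p = 0.0296). They were Gng2 (1.29 ± 0.35 in DeltaMxCre and 0.66 ± 0.14 in DeltaTamCre; adjusted p = 0.0381 and 0.119), Samd8 (0.51 and 0.29; 0.122 and 0.184), D14Abb1e (0.65 and 0.35; 0.00455 and 0.153), Sh3bp5 (0.87 and 0.43; 0.0306 and 0.142) and Ogdhl (−1.13 and −0.64; 0.0548 and 0.0992). None passed in DeltaTamCre, Samd8 and Ogdhl did not pass in DeltaMxCre, and the interval of the odds ratio includes 1. Gng2 also rose in AntiNRR (1.18), a comparison of antibodies, so its rise was not particular to the deletions. DNA of another strain carried along with the floxed allele may contribute, as a hypothesis formed on these data.

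Ribosomal protein genes were high in replicate 1 of the 4 SMARTer groups, 0.18 to 0.23 above their group means (mean 0.2, exact 2-sided p = 0.0123, the smallest of 81 assignments). A shared handling step for these libraries could produce this, and none is given in the sources used here.

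The ribosomal RNA precursor Rn45s moved in opposite directions in DeltaMxCre and AntiNRR. It made up 4.71 to 5.07% of counts in DeltaMxCre and 6.76 to 8.82% in MxCre, and rose in AntiNRR (0.90 ± 0.13, adjusted p = 0.000149), from 2.75 to 3.74% in IgG to 4.77 to 6.80%. In DeltaTamCre it did not pass (−0.44 ± 0.35, adjusted p = 0.58).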
